A study of Homo sapiens with 2 samples.

How the data were processed

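The data came from chromatin immunoprecipitation followed by sequencing (ChIP-seq) in SW620, an established human cell line derived from a lymph node metastasis of a colorectal adenocarcinoma. The antibody was raised against WSTF, the product of BAZ1B, a bromodomain protein that pairs with the ISWI ATPase SMARCA5 in chromatin remodelling complexes. The series holds 2 samples, 1 titled with the suffix IP and 1 without it. The second sample was not treated as the input here, because its title and annotations do not name it so. The title of the series speaks of WSTF knockdown and its design text of WSTF overexpression, so the level of WSTF in the cells is left open. Per the labels' protocols, chromatin was fixed with 1% formaldehyde for 10 min, sheared to between 200 and 500 bp and immunoprecipitated, and the DNA was recovered after heating at 65 °C.

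Per the submitters' processing notes, the tools were Trimmomatic 0.39, Bowtie2 2.4.4 and MACS2 2.2.7.1, and the build was hg38. Per the design text, MACS2 was run against input DNA. Whether replicates were pooled before peak calling is not given in the sources used here; the design text mentions several biological replicates, and a single list was analysed. The deposited list gives 1 base per peak, the summit, with a score. The score was read as −log10 of the peak caller's q-value, because the deposited −log10 values start at 1.31, just above the 1.30 that corresponds to a q of 0.05. The score is the authors' own and was used only within the list, to describe, rank, filter and compare summits, singly or by chromosome. It is not a measure of occupancy that can be compared with another sample. The list holds no reads or coverage, so the sequencing depth is unknown and the p-values below compare positions with random positions, not samples with samples.

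Summits were compared with the RefSeq gene table of assembly GRCh38.p14, which uses the same chromosome coordinates as hg38. Of 59792 genes in that table, the 59679 on chromosomes 1 to 22, X and Y were used. Moving all summits by 5 kb lowered the share within 1 kb of a gene boundary from 80.5% to 13.8%, so the coordinates of the list and the table match. The table gives the outer start and end of each gene but neither strand nor exons. The planned tests on transcription start sites were therefore run on gene boundaries, meaning either end of a gene. Each summit was placed in 1 of these classes, in order: within 1 kb of a boundary of any gene, inside a protein-coding gene, inside another gene, or intergenic. Promoters inside the outer limits of a gene count as gene body. The 5′ end was told apart from the 3′ end only for genes of at least 5 kb that have a divergent transcript named after them (symbol ending in DT) within 5 kb of an end. By naming convention such a transcript starts beside the gene's promoter.

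Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Observed shares were compared with 1000 placements of as many positions, drawn uniformly on the same chromosomes up to the end of the last gene, in two-sided permutation tests whose smallest p is 0.002. Boundary windows other than 1 kb were described with 200 placements, and lncRNA genes, pseudogenes and protein-coding genes as classes were tested with 100 local shifts, whose smallest p is 0.0198. Summits away from boundaries were compared, in a test chosen after seeing the data, with those of 1000 placements of the same summits that also fell away from boundaries. A genome sequence was not used here, so assembly gaps were not excluded and GC content and repeats were not matched. A second background, chosen after seeing the data, moved each summit by 10 to 500 kb at random and so kept the regional gene density. Counts per chromosome were compared with the length up to the last gene by two-sided exact binomial tests. The share of protein-coding genes with a summit within 1 kb of either end was compared between each chromosome, each 5 Mb stretch with at least 20 genes, or each family of symbols with at least 20 genes, and the rest by two-sided Fisher's exact test. These tests by gene were also chosen after seeing the data, and they treat neighbouring genes as independent. Scores of boundary and other summits were compared by a two-sided permutation test of the medians with 100000 resamples. P-values were adjusted after Benjamini and Hochberg over annotation classes, chromosomes, 5 Mb stretches, symbol families, gene classes and gene lists. The other p-values, such as those for the boundary share, clustering, scores and divergent transcripts, were not adjusted.

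The 12 gene lists were fixed before the data were examined, and all 371 of their entries, given by symbol or by a symbol pattern, matched a protein-coding gene. For each list, the number of genes with a summit in the gene or within 1 kb of it was compared with 10000 random lists matched on gene length in 10 bins (two-sided permutation test). Genes with a summit within 1 kb of either end were also counted with Fisher's exact test. Genes named in the text follow a rule fixed beforehand: the 10 highest-scoring summits, the 15 highest-scoring summits within 1 kb of a protein-coding gene boundary, up to 4 members per list by score, BAZ1B and SMARCA5 whatever their values, and the 5 genes holding the most summits. Some genes that this rule selects are not reported here. Where 1 summit lies near several genes, the gene with the nearest boundary is named. The scripts were tested on simulated positions and lists. Planting 5% of 2697 random positions at boundaries gave a share of 12.0% where 11.7% was expected, and 5% of unchanged simulations were called at p below 0.05. Simulated lists of 20 genes had 40% of their genes given a summit, on top of any summits present by chance. Of these lists 61% were called, against 0% of unchanged lists. The adjustment there ran over a larger set of lists than the 12 tested here, so 61% is not the power of the real test. Alternatives covered stricter score thresholds, other windows, merging of close summits, other backgrounds and removal of the highest scores. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.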

Results

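The genome-wide locations of WSTF in SW620 colorectal cancer cells were represented by a single list of 2697 ChIP-seq peak summits. All lay on chromosomes 1 to 22 and X. No replicate lists were analysed, and the sequencing depth is unknown. The comparisons the list allows are therefore between summit positions and genome annotation, and between summits of different score.

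The strongest summits included a few loci far above the rest. The summit with the highest score, 5479 on the −log10 q scale, lay at chromosome 14 position 105742045 (hg38), inside IGHG1, the immunoglobulin gamma-1 heavy chain constant region (105741473 to 105743070). The gamma heavy chain genes are near-identical copies, so reads could have been shared between them and the assignment to IGHG1 is uncertain. The next lay at chromosome 11 position 66421794 inside NPAS4, an activity-regulated neuronal transcription factor gene, with a score of 342. The summit after these scored 190 and lay 36 bp outside HDX, at position 84502489 on chromosome X. The remainder of the 10 highest scores ran from 44.2 at XKR7 to 16.9 at SLC9D1. They included MIR7-3HG (41.5), the host gene of a miR-7 precursor, VRK3 (22.4), RAB22A (19.2), the synaptic gene CPLX2 (18.8) and the serotonin receptor gene HTR5A (17.8).

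Most summits had modest scores. The median was 3.72, the lower quartile was 2.76, and 42 summits (1.56%) reached 10. Scores were often tied: the 2697 summits shared 813 distinct values, and 91 summits carried the value 3.02.

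**Figure D1:**
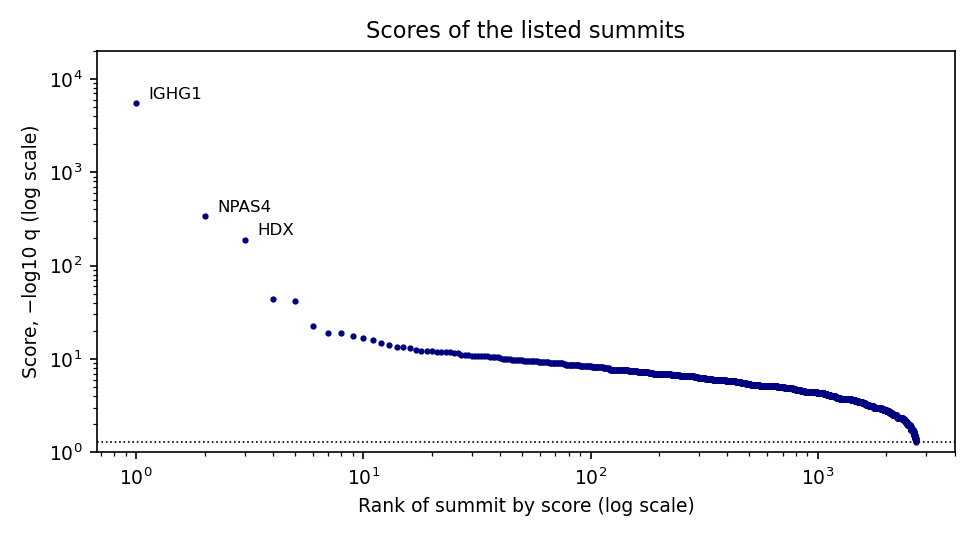
Score of each summit (−log10 q, log scale) against its rank in the list (log scale), each point being 1 of 2697 summits and the dotted line marking a q of 0.05. The summits at IGHG1, NPAS4 and HDX, at 5479, 342 and 190, stand apart from the fourth, at 44.2.

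The position of summits relative to genes was examined by comparing them with randomly placed positions. Summits lay predominantly at the ends of genes: 2172 of 2697 (80.5%, 95% interval 79.0 to 82.0) were within 1 kb of the start or end of an annotated gene. Random positions on the same chromosomes gave 7.11% ± 0.48 (SD, 1000 placements), a ratio of 11.3 (permutation test, p = 0.002, the smallest possible). For protein-coding genes alone the share was 73.2% (71.4 to 74.8) against 3.07% ± 0.33 at random. The summits were also close: 57.6% lay within 250 bp of a boundary, where random positions gave 2.03%. Against summits moved locally by 10 to 500 kb, which keeps the regional gene density, the 1 kb share was still 7.13 times the 11.3% expected. Neither background was matched on GC content or open chromatin. The excess therefore describes called summits, and WSTF binding is not separated from open chromatin shared by active promoters.

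The boundary excess left 525 summits for the other classes, which held down their shares of all summits: 13.8% (12.5 to 15.2) in bodies of protein-coding genes, 1.15% in bodies of other genes and 4.49% in intergenic sequence, against 41.1%, 11.1% and 40.6% at random. The 525 were therefore compared with random positions that also lay away from boundaries. Bodies of protein-coding genes held 373 of them (71.0%, 67.0 to 74.9), against 44.6% ± 2.19 at random and 59.0% ± 2.10 after local shifts (adjusted permutation p = 0.002 and 0.003). Intergenic sequence held 121 (23.05%) against 43.5% ± 2.23, and bodies of other genes 31 (5.90%) against 11.96% ± 1.44 (both adjusted permutation p = 0.002). These 3 shares sum to 100%, so they are not independent. Of the 525 summits, 252 lay more than 5 kb from any boundary. The random positions were not matched on distance to a boundary, and promoters inside a gene count as gene body. The gene-body excess is therefore not separated from the boundary excess.

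**Figure D2:**
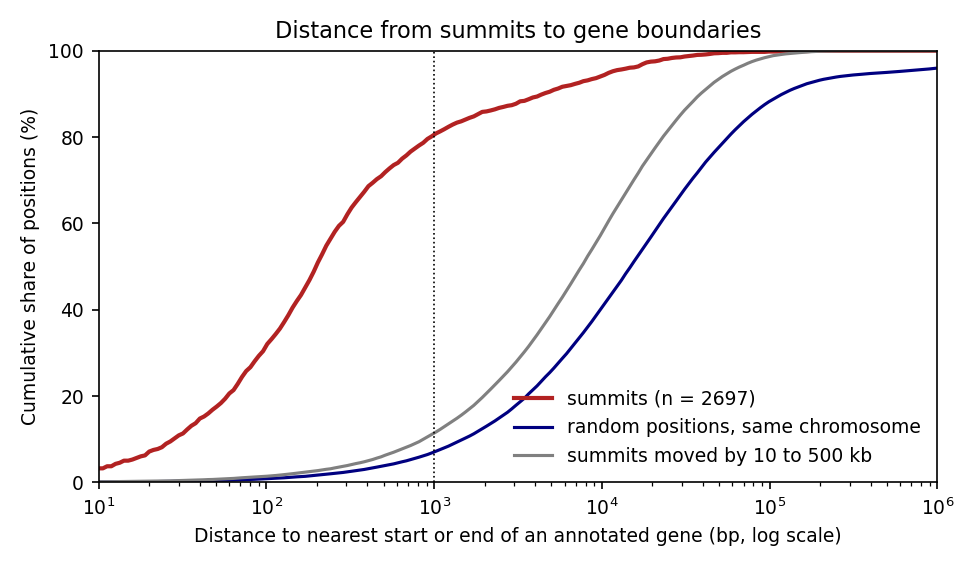
Cumulative share of positions (%) within a given distance (bp, log scale) of the nearest start or end of an annotated gene, for the 2697 summits and for positions placed at random on the same chromosomes or moved by 10 to 500 kb. At the dotted line (1 kb) the summits reach 80.5%, random positions 7.11% and moved summits 11.3%.

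The gene table carries no strand, but divergent transcripts marked the promoter end of 527 genes. At these genes 107 (20.3%, 16.9 to 24.0) had a summit within 1 kb of the end beside the divergent transcript, and 4 (0.76%, 0.21 to 1.93) had one at the opposite end. The difference was larger than counting error (106 genes with a summit at the promoter end alone against 3 at the opposite end alone, exact McNemar test, p = 6.7e-28). Open chromatin at promoters was not matched in this comparison either and could give the same difference. The nearest summit lay at a median of 63 bp inside the gene, with quartiles from 127 bp outside to 177 bp inside. Among protein-coding genes of at least 5 kb with a boundary summit, 2036 had it at 1 end and 22 at both.

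In all, 2321 of 19974 protein-coding genes (11.6%, 11.2 to 12.1) had a summit within 1 kb of an end. After HDX, XKR7, RAB22A, CPLX2, HTR5A and SLC9D1, the next boundary summit by score lay 307 bp from LUC7L2, a splicing factor gene, with a score of 14.9. Others were KLF11 (14.0), TCF3 (13.4), DPF2 (13.2), a subunit gene of the BAF remodelling complex, ZNF274 (12.1) and CTCF (12.1), which encodes the insulator protein. The amino acid transporter gene SLC7A6 (13.4), the ESCRT ATPase gene VPS4A (12.5) and the chaperonin gene CCT6A (12.1) completed the 15. Their summits lay between 36 and 492 bp from the gene boundary.

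Few genes held several summits. A single summit fell in or within 1 kb of 2601 protein-coding genes, 151 genes held 2 and 13 held 3. The highest-scoring of these 13 were SLC16A3, a lactate transporter gene, SOD2, the mitochondrial superoxide dismutase gene, ITPR2, BCAR1 and LRRC56.

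BAZ1B itself, which encodes WSTF, had summits at chromosome 7 positions 73521830 and 73522265, 463 and 28 bp from its outer end, with scores of 3.02 and 1.73. No other summit lay in the gene (73440406 to 73522293). SMARCA5, the gene of its ATPase partner on chromosome 4, had none within 1 kb. The nearest summit on that chromosome lay 39946643 bp away, so the absence covers a wide stretch and is not particular to SMARCA5.

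Summits within the list were also compared by score. Boundary summits had a median score of 3.72 and the 525 others 3.58, a difference of 0.14 (permutation test of medians, two-sided, p = 0.0125). With a boundary window of 5 kb it was 0.33 (permutation p = 0.0034). Among summits at or above the median score, a selection on the value being compared, it was 0.02 (permutation p = 0.94).

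Which pathways carried summits was examined with the 12 gene lists. None passed the threshold against length-matched random lists after adjustment (permutation test, adjusted p at least 0.060), and 1 passed at an unadjusted p below 0.05. This was growth factor and RAS-PI3K signalling, in which 10 of 26 genes (38.5%, 20.2 to 59.4) had a summit against 3.90 ± 1.81 expected (permutation p = 0.005, adjusted permutation p = 0.060). Its members with high-scoring summits included the kinase gene BRAF (6.16), 166 bp from the gene end, and RICTOR (4.79), 29 bp from it. Counting gene ends alone, 9 of 26 members had a summit, and this list passed (Fisher's exact test, adjusted p = 0.022). That test was matched on neither gene length nor expression, and the length-matched tests were not matched on expression either.

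Lists of chromatin, replication and repair genes had more summits than expected without passing the test. The list of WSTF and its partners had 6 of 17 genes with a summit against 2.68 ± 1.49 (adjusted permutation p = 0.24), with SMARCB1 (5.14), MYO1C (4.91), SMARCA4 (4.44) and RSF1 (4.04) scoring highest. DNA damage response genes had 7 of 23 against 3.57 ± 1.72 (adjusted permutation p = 0.26), including the checkpoint kinase genes ATR (5.10) and ATM (4.68), the ubiquitin ligase gene RNF168 (4.90) and NBN (3.00). Cell cycle and replication genes had 7 of 26 against 3.70 ± 1.80 (adjusted permutation p = 0.26). There the replication clamp gene PCNA had the highest score (9.61), followed by POLA1 (5.20), CDKN1B (3.78) and E2F1 (3.44). Glycolysis had 6 of 17 against 2.48 ± 1.48 (adjusted permutation p = 0.24), with summits at ENO1 (4.93), SLC2A1 (4.67), GPI (4.12) and TPI1 (3.96).

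Lists tied to colon cancer progression did not stand out. The Wnt/beta-catenin list had 3 of 27 genes with a summit against 3.77 ± 1.79 (adjusted permutation p = 0.95): MYC (5.68), SP5 (3.76) and DKK4 (2.97). The epithelial-mesenchymal transition list had 3 of 27 against 3.88 ± 1.81 (adjusted permutation p = 0.95): ITGB1 (5.82), VIM (5.78) and TGFBR2 (2.83). Intestinal identity genes had 2 of 19 against 2.78 ± 1.54 (adjusted permutation p = 0.95), KLF5 (6.14) and KRT19 (2.36). Ribosomal protein genes had 12 of 83 against 9.54 ± 2.90 (adjusted permutation p = 0.64), led by RPL27A (6.27), RPL10A (5.21), RPL39 (5.15) and RPS3 (4.85). Replication-dependent histone genes had 2 of 69 against 5.12 ± 2.12 (adjusted permutation p = 0.34), H4C16 (4.04) and H4C4 (3.17). No summit was found at the 12 genes of the list of the vitamin D receptor and its targets (interval to 26.5%, adjusted permutation p = 0.57) or the 25 markers of unrelated tissues (interval to 13.7%, adjusted permutation p = 0.24). In simulation, lists of 20 genes were called 61% of the time when 40% of genes were given a summit. Those summits came on top of any present by chance, and the p-values were adjusted over a larger set of simulated lists. The 61% is therefore not the power of the list tests above and may overstate it.

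**Figure D3:**
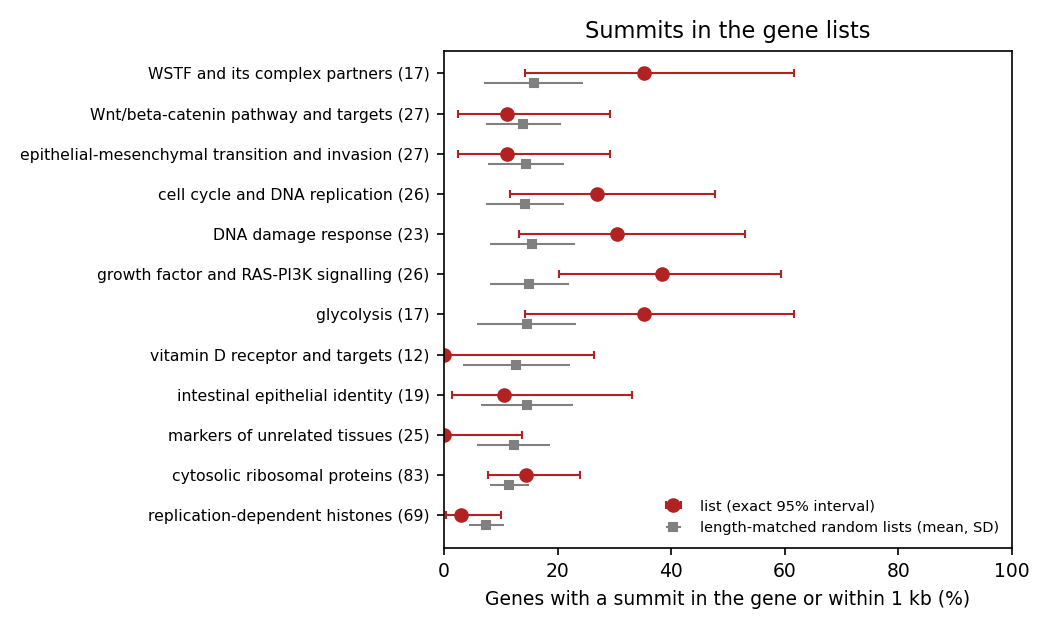
Share of genes (%) in each of the 12 lists with a summit in the gene or within 1 kb (circles, exact 95% intervals; list sizes in brackets) beside length-matched random lists (squares, mean and SD). Growth factor and RAS-PI3K signalling, at 38.5%, lies farthest from its random lists relative to their SD.

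Summits were spread unevenly over chromosomes. Relative to length, 7 chromosomes held more and 11 fewer summits than expected (exact binomial test, adjusted p below 0.05, 23 chromosomes). Chromosome 19 had 171 summits, 3.28 times expected, and chromosome 17 had 227, 3.06 times expected. Chromosome 18 had 11, or 0.154 of expected. Because these chromosomes differ in gene density, the share of protein-coding genes with a boundary summit was compared as well. It was highest on chromosome 20 (128 of 537 genes, 23.8%, 20.3 to 27.7), followed by chromosome 16 (19.4%), 11 (17.5%), 17 (17.5%), 13 (16.0%) and 10 (15.3%), all above the remaining genome (Fisher's exact test, adjusted p at most 0.029). It was lowest on chromosome 18 (10 of 270 genes, 3.70%, 1.79 to 6.71) and X (33 of 848, 3.89%, 2.69 to 5.42). The 2 comparisons disagreed on chromosome 13, which held 0.648 of the summits expected from its length. Chromosomes 21, 4, 15, 6 and 1 were also below the remaining genome, and chromosome 19 was not past the threshold (10.3%, Fisher's exact test, adjusted p = 0.14).

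**Figure D4:**
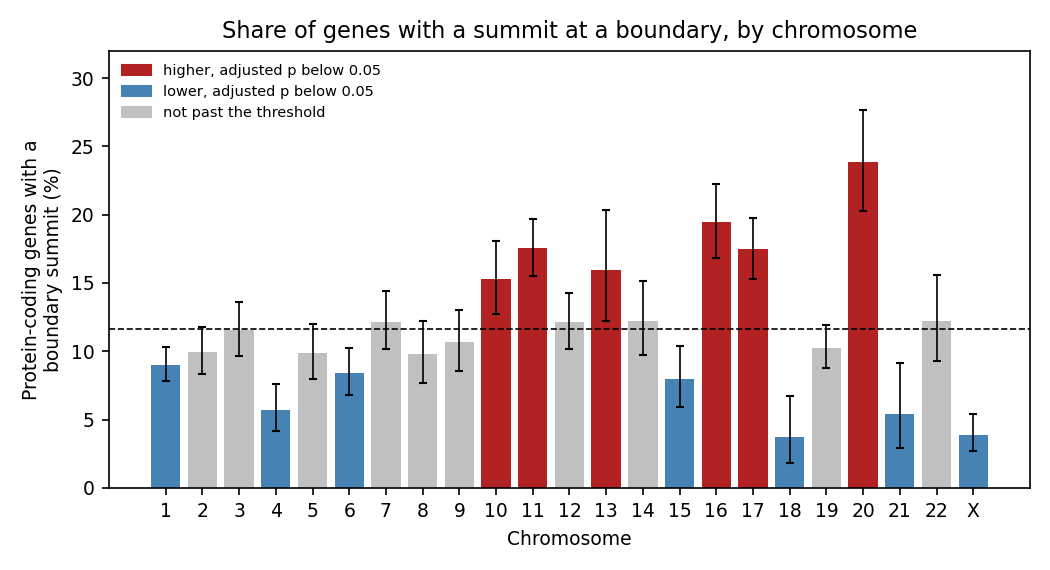
Share of protein-coding genes (%) with a summit within 1 kb of either end on each chromosome, with exact 95% intervals, coloured by Fisher's exact test against the remaining genome; the dashed line is the share over all chromosomes (11.6%). Chromosome 20 reaches 23.8%, and chromosomes 18 and X stay at 3.70% and 3.89%.

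Summits also lay near each other. Another summit lay within 10 kb of 286 summits (10.6%), against 70.8 ± 11.6 in random placement and 191 ± 17.5 after local shifts (permutation test, p = 0.002 for both). Neither background kept the observed share of summits at gene boundaries. The excess of close summits is therefore not separated from the boundary excess reported above.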

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

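Of 53 alternative values computed for the main results, 47 kept their direction and call or, for a count, stayed within 1.5 times the main value. An unchanged count does not mean that the same chromosomes passed. The boundary share stayed between 71.7% (window of 500 bp) and 90.7% (window of 5 kb) under 9 alternatives and above its background in each. The clustering of summits kept direction and call throughout, as did the protein-coding body and intergenic shares of summits away from boundaries. The share of those in bodies of other genes, 5.90%, was 8.16% among the 270 highest-scoring summits (adjusted permutation p = 0.37). As shares of all summits these classes are held down by the boundary excess, so their stability gives no separate support. The number of chromosomes that departed from their length fell from 18 to 11 when the 270 highest-scoring summits alone were used, a setting with fewer summits to test. It was 14 when expectations came from the number of protein-coding genes, chosen after seeing the data, and 3 chromosomes changed direction there. Chromosome 13 went from 0.648 of expected to 1.45 (adjusted exact p = 0.0084), chromosome 19 from 3.28 to 0.873 (adjusted exact p = 0.099) and chromosome 22 from 1.33 to 0.985. The higher median score of boundary summits, 0.14, was 0.33 with a boundary window of 5 kb (permutation p = 0.0034). It was 0.02481 among summits at or above the median score, an alternative chosen after seeing the data that selects on the score itself. The count of gene lists past the threshold, 0 in the main setting, was 1 when gene ends alone were used, 1 with 10 kb either side of the gene and 2 without length matching. In each of these the growth factor and RAS-PI3K list passed (adjusted permutation p = 0.026, 0.041 and 0.034), while it did not among summits at or above the median score, where 6 of 26 genes had a summit at a ratio of 3.09 to random lists against 2.56 for all summits (adjusted permutation p = 0.28). Without length matching the histone list also fell below random lists (adjusted permutation p = 0.034). Leaving out the 3 highest-scoring summits changed none of the boundary share, the clustering or the list calls. The alternatives that need a genome sequence, namely GC-matched placement and repeat masking, were not run, and the share of summits in repeats was not computed. No paired analysis was possible because a single list of summits with no replicates was analysed. The read depth is unknown, so a gene without a summit is not shown to lack WSTF.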

Other observations

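Tests in this part that were chosen only after their results had been seen are those on the 3 highest summits; the gene families, gene classes other than tRNA and 5 Mb stretches were also chosen after the list had been inspected.

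Gene families sorted by symbol differed in how often they carried a boundary summit. Among 98 families, 1 was above and 4 were below the remaining protein-coding genes (Fisher's exact test, adjusted p below 0.05). DDX genes, which encode DEAD-box RNA helicases, had a summit at 11 of 37 members (29.7%, 15.9 to 47.0, exact test, adjusted p = 0.048). The highest scores among them were at DDX28 (6.52), DDX50 (5.54) and DDX5 (5.20). The family tests were not matched on chromosome, gene length or expression, and chromosomes differed in their share of genes with a summit. A preference for RNA helicase genes is therefore not shown. Olfactory receptor genes (OR) had none at 392 members (interval to 0.94%, exact test, adjusted p = 8.1e-20), keratin-associated protein genes (KRTAP) none at 94 (adjusted p = 4.7e-04) and cytochrome P450 genes (CYP) none at 56 (adjusted p = 0.048). The fourth depleted family was the placeholder symbols starting with LOC (38 of 639).

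Some classes of non-coding genes differed as well. Of 14098 lncRNA genes farther than 2 kb from any protein-coding boundary, 125 had a summit within 1 kb of an end, against 60.7 ± 8.6 after local shifts (permutation test, adjusted p = 0.031). Pseudogenes not annotated as transcribed went the other way, with 6 of 14440 against 43.9 ± 7.5 (adjusted permutation p = 0.031). For both classes the unadjusted p was 0.0198, the smallest that 100 shifts can give. Summits within 1 kb of a protein-coding boundary cannot count at genes this far from one. They made up 73.2% of the summits but 6.07% after local shifts. The counts of every class at this distance are thereby held down, so the low pseudogene count was partly fixed in advance. Transcribed pseudogenes were above, with 13 of 1041 against 5.27 ± 2.17 (adjusted permutation p = 0.017), as were miRNA genes, with 14 of 1562 against 5.69 ± 2.60 (adjusted permutation p = 0.031). At the same distance, snoRNA genes (2 of 1040 against 3.14 ± 1.89, adjusted permutation p = 0.96) and snRNA genes (1 of 141 against 0.405 ± 0.649, adjusted permutation p = 0.85) did not pass the threshold. No summit lay at the 49 annotated rRNA genes (interval to 7.25%), where 0.162 were expected, so this count cannot show a difference. A summit near several genes counts for each of them, so the lncRNA and miRNA counts can share summits. The summit at MIR7-3HG, for example, also lay within 1 kb of the miRNA gene MIR7-3. Separate summits were counted only for tRNA genes.

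The 3 summits at IGHG1, NPAS4 and HDX exceed all others, the third of them scoring 4.30 times the fourth. Amplification of a wide genomic segment was taken to predict many neighbouring summits. IGHG1 had 4 and HDX 0 within 500 kb, at or below the 71.0 percentile of all summits, so the prediction was not met there. The neighbour counts were not matched for local gene density, however. A locus with few genes nearby would have few neighbouring summits with or without amplification, so these counts cannot decide. NPAS4 had 12 neighbours, at the 94.0 percentile, just short of the 95 that amplification was taken to need, so for NPAS4 this cannot be told apart from a gene-rich region. The strongest neighbour scored 7.71 near IGHG1 and 8.32 near NPAS4. Foreign DNA carrying the same sequence, such as an expression construct or amplicon, may also give such summits: 1 of the 3 lay within 1 kb of a protein-coding gene boundary and 2 within 1 kb of a boundary of any gene (572 bp at IGHG1, 36 bp at HDX and 4913 bp at NPAS4). These distances do not decide for or against it, since fragment ends were not analysed here.

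The uneven spread over chromosomes was not accounted for by the number of genes alone, because the share of genes with a summit itself differed (chi-square permutation p = 0.0001, the smallest possible). This difference also held without the 4 depleted families (permutation p = 0.0001). Those families were picked by their low share in the same data, and other families with few summits were kept. Removing them therefore cannot decide whether such families account for the difference. A summit between close gene ends counts for each of those genes, and 1973 summits gave 2321 genes with a boundary summit. The share can therefore still depend on how closely genes are packed. Among 368 stretches of 5 Mb, 26 were above and 12 below the genome, with the highest share on chromosome 17 from 80 to 85 Mb, where 38 of 78 genes (48.7%, 37.2 to 60.3) had a summit. Chromosome 16 from 65 to 70 Mb, with the smallest p, had 46 of 97 (47.4%, 37.2 to 57.8) and chromosome 11 from 65 to 70 Mb had 47 of 140, while chromosome 6 from 25 to 30 Mb had 1 of 118. DNA copy number of the cell line is a candidate explanation that stays open: chromosomes with a higher share had a median score that was not detectably higher (Spearman rho 0.28, permutation p = 0.19; Pearson r 0.38, p = 0.075; r 0.29 without the 2 most extreme chromosomes, p = 0.20; 23 chromosomes), and a regional difference in WSTF binding was not tested.

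WSTF has been described in complexes that act on RNA polymerase III genes, and the hypothesis that tRNA genes carry summits was tested. Of 368 tRNA genes farther than 2 kb from any protein-coding boundary, 7 (1.90%, 0.77 to 3.88) had a summit within 1 kb, against 1.49 ± 1.30 after local shifts (permutation test, p = 0.012, adjusted p = 0.031 over 17 overlapping tests of 9 gene classes). These were 7 separate summits on 4 chromosomes, 5 of them more than 1 kb from the boundary of any other gene; their scores ran from 3.13 to 4.68. The excess is consistent with WSTF at some tRNA genes, but open chromatin shared by all active promoters was not tested and could give the same count, and reads of near-identical tRNA copies may be misplaced.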
